A study of Caenorhabditis elegans with 10 samples.

How the data were processed

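ChIP-seq peak lists of CEH-60, UNC-62 and PQM-1 from whole day 1 adults of C. elegans were used as deposited, 1 list for each of 8 immunoprecipitated samples, with 40986 peaks in all. Samples were grouped by strain, antibody and replicate as the labels give them, which made 7 groups with a list; the 2 input samples had no list in use and were not analysed here. Per the labels' protocols, animals of protocol 1 were grown at 20 °C, and the growth temperature for protocol 2 is not given in the sources used here. Protocol 1 used 2% formaldehyde over 30 min, Bioruptor shearing and the KAPA kit, and protocol 2 used 1% formaldehyde over 5 min, Covaris shearing and the ThruPLEX kit. Each protocol gave 4 of the lists. A longer crosslinking can hold indirectly bound DNA as well, so the pairs of lists lie within a protocol except for the CEH-60 replicates. The count of sites with all 3 factors, the distances of PQM-1 summits from CEH-60 replicate 1 summits and the split of PQM-1 peaks by a CEH-60 replicate 1 peak also cross protocols.

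Per the submitters' processing notes, Bowtie2, SAMtools, MACS2 and deepTools were used by the authors, without versions. The genome build, the control library of each peak call, duplicate removal and the placing of reads that match several sites are not given in the sources used here. Each list belongs to 1 sample, so peaks were called per sample. The deposited lists hold, for each peak, its interval, a score, a fold enrichment, 2 values of −log10 and the summit. The score deposited by the authors was 10 times the −log10 q-value, shortened to a whole number, and was not used further. The fold in the deposited lists is a ratio of the signal at the summit to the local background, on a linear scale. The −log10 p-value and −log10 q-value in the deposited lists refer to the summit, and no −log10 q lay below 2. Read depth is unknown, so shares of peaks have Wilson 95% intervals that cover counting error only, and the numbers of peaks limit the precision.

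Analyses used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9, with the random seed 7. No intervals were repeated within a list (0 peaks shared an interval). Peaks of the 6 nuclear chromosomes were compared, and those of the mitochondrial chromosome were counted apart. Peaks overlapped where they shared 1 bp or more. The chance level was the mean of 1000 placements of the other list at random positions of the same chromosome, with peak lengths kept. Gene names and neighbours came from a table of the assembly WBcel235, with 19971 protein-coding genes among 46890 nuclear genes. To test whether the lists and the table share a coordinate frame, genes were shifted in steps against the summits, and the best shift over 14 sets was between −40 and 30 bp, with a median size of 20 bp. No coordinate of that table is printed.

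A gene was called bound where a summit lay from 1000 bp outside to 200 bp inside either of its ends. A rule for promoters on the 5′ side and classes of exon, intron and UTR had been fixed, but the table gives neither strand nor exons. Gene ends, and positions between or inside protein-coding genes, took their place. The motif test that had been planned was not run, since no genome sequence was used here. Overlaps of bound genes were set beside the product of both counts divided by the number of protein-coding genes. There were 28 gene lists, 14 of named genes and 14 of families by symbol, and 1338 of 1339 members were found in the table. A few genes are in more than 1 list, as elt-2 is in 3. For each list and library, the number of bound members was ranked among 10000 random lists of protein-coding genes matched on quintile of the summed distance to both neighbouring genes, and called above or below where under 2.5% of random lists were as extreme. These ranks describe the libraries and are not p-values. After the values were seen, the share of list members' peaks that a further list also had was set beside 10000 draws of peaks matched on decile of fold. For these shares and draws, each bound gene gave its gene-end peak of highest fold, and its weaker peaks were left out.

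Named genes are those of the 10 peaks of highest fold among shared peaks of the first list of a pair, counting peaks with a bound protein-coding gene and passing over those without one, its 10 highest unshared peaks and the 10 highest unshared peaks of the other list, at most 30 per comparison, with the vitellogenins, ceh-60, unc-62 and pqm-1 in every list and up to 4 bound members of highest fold for each gene list. From these, some are left out for length. Genes named as bound in every list, and those named with the counts of peaks found in a further list, were chosen after their values were seen. The gene lists, pairs of lists, overlap rule and naming rule were set before the data were examined, and the limit of 2.5% was not among them.

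Overlaps, chance levels at random positions, gene lists called above and fold-matched draws called below were tested on simulated lists. The other steps and directions were not. Planted overlaps of the 7 pairs were recovered within 0.0244 percentage points in 21 simulations, and chance levels within 0.0918 points. Of unchanged lists of 12 or 40 genes at most 2% were called above in any of the 8 libraries. Lists planted at 2.5 times the bound share were called in 0 to 100% of simulations, depending on the library, so a list on neither side in a short peak list shows little. In the draws of 5 peaks from the 6001 PQM-1 peaks of OP201, random sets were called below in 0.6% of simulations and sets of 5 lost peaks in 60%.

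Alternatives were an overlap of at least 50% of both peaks, peaks with a −log10 q of 5 or more, the 1000 peaks of highest fold of each list, leaving out peaks within 500 bp of 1107 genes of structural RNA, gene-end distances of 500 and 2000 bp, unmatched random lists, and each CEH-60 replicate left out of the count with all 3 factors.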

Results

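Chromatin immunoprecipitation followed by sequencing (ChIP-seq), which recovers the DNA bound by a protein, was carried out on whole day 1 adults of the nematode C. elegans for 3 transcription factors. CEH-60 is a homeodomain protein of the PBX family, UNC-62 is a homeodomain protein of the MEIS family, whose members bind DNA together with PBX proteins, and PQM-1 is a zinc finger protein of the intestine. CEH-60 was recovered through an HA tag at its own gene, in the strain DLS395 (ceh-60(rhd116)), with the antibody 3F10 in 2 libraries (replicates 1 and 2) and with a further anti-HA antibody, mIgG1, in 1 library. The strain DLS396 carries the tagged ceh-60 together with the unc-62 transgene gaIs285 and gave a CEH-60 list and an UNC-62 list, the latter with an antibody to GFP. PQM-1 was recovered through the FLAG tag of the transgene wgIs201 in the strain OP201, and in DLS422, which carries the deletion allele ceh-60(ok1485). CEH-60 was also recovered in DLS435, which carries the deletion allele pqm-1(ok485). These strains are called without ceh-60 and without pqm-1 for short. Of the 10 samples, the 8 immunoprecipitations each had 1 peak list and were analysed, and they fall into 7 groups. The 2 input samples, from DLS395 (protocol 1) and OP201 (protocol 2), were not analysed here. CEH-60 replicate 1, the mIgG1 library and both DLS396 libraries were made by protocol 1, with long crosslinking, and CEH-60 replicate 2, DLS435 and both PQM-1 libraries by protocol 2, with short crosslinking.

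Read depth is unknown, so the number of peaks is the nearest measure of how much each library recovered. The lists held 9010 peaks for CEH-60 replicate 1, 4431 for the mIgG1 library, 8993 for CEH-60 in DLS396 and 2053 for UNC-62. In protocol 2 they held 6001 peaks for PQM-1 in OP201, 5020 for PQM-1 in DLS422, 3430 for CEH-60 replicate 2 and 2048 for CEH-60 in DLS435. Each peak has a fold enrichment, which is the authors' own value for the peak summit over its local background. It is used here to describe, rank and filter peaks within a list and is not compared between lists. The median fold was 4.52 (range 1.72 to 21.1) in CEH-60 replicate 1 and 2.38 (range 1.45 to 6.65) in the OP201 PQM-1 list. Apart from CEH-60 in DLS395 with 3F10, each group had 1 library, so those comparisons have no replicate check and no p-value is given. Wilson 95% intervals on shares of peaks cover counting error only. A gene is called bound where a peak summit lay from 1000 bp outside to 200 bp inside either of its ends, since gene strand was not used here. Peaks named as the strongest of a class are the strongest of those with a bound gene, and stronger peaks without one are not named. Coordinates are 1-based and are those of the deposited lists, whose genome build is not given in the sources used here.

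The vitellogenin genes vit-1 to vit-6, which encode the yolk proteins made by the adult intestine, were bound in every CEH-60 list and in the UNC-62 list, 6 of 6 genes in each. In CEH-60 replicate 1 their strongest peaks had folds of 16.3 to 20.99 and ranked from 2 (vit-2) to 93 (vit-4) among 9008 nuclear peaks. Those peaks lay at X 7727127 to 7730066 (vit-1), X 5100143 to 5103079 (vit-2), X 3572255 to 3573275 (vit-3), X 3563860 to 3565263 (vit-4), X 3402795 to 3405198 (vit-5) and IV 8260559 to 8266977 (vit-6). PQM-1 peaks in OP201 bound vit-1 to vit-5, 5 of 6 genes, with folds of 2.13 to 3.03. At vit-6, a 6843 bp OP201 peak (IV 8260607 to 8267449) lay along the gene with its summit 2084 bp from that of CEH-60. In DLS422, without ceh-60, PQM-1 peaks bound none of the 6 genes. The nearest DLS422 peak (X 3557516 to 3557860, 2.5-fold) lay by vit-4, 6463 bp from the CEH-60 summit. vit-3, vit-4 and vit-5 are near-identical copies, and how reads that match several copies were placed is not given in the sources used here, so these genes are not independent loci.

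**Figure D1:**
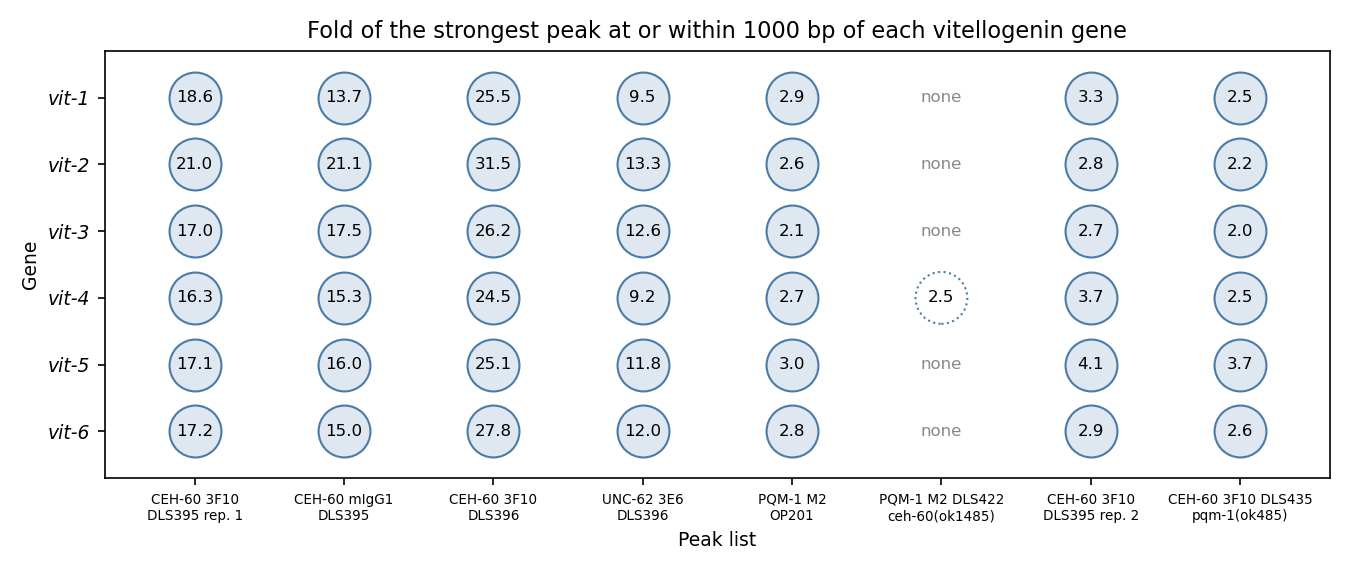
Fold of the strongest peak (no unit, number in each circle) at or within 1000 bp of each of the 6 vitellogenin genes (vertical axis) in each of the 8 peak lists (horizontal axis). The word "none" marks a gene without such a peak, and folds are not comparable between lists. All 6 genes have a peak in the 5 CEH-60 lists, the UNC-62 list and the OP201 PQM-1 list, while the DLS422 list has 1, dotted, at vit-4, which lies 6463 bp from the CEH-60 summit.

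The tagged and deleted genes serve as a check of the labels. A peak by ceh-60 was present in every list, at X 6530224 to 6531647 in CEH-60 replicate 1. PQM-1 in OP201 had 2 further peaks with summits inside ceh-60, at X 6522577 to 6523102 and X 6524820 to 6525053, and PQM-1 in DLS422, labelled ceh-60(ok1485), had 0 there. The extent of that deletion was not used here. Both PQM-1 lists, from strains that carry wgIs201, had peaks over 97.0% or more of pqm-1, with the strongest at II 11150722 to 11156744 in OP201 and II 11150718 to 11156757 in DLS422. Without wgIs201, the CEH-60 peaks of replicate 1 lay over 76.1% of pqm-1 and those of DLS396 over 54.6%, in 4 and 3 shorter peaks, so coverage alone does not check that label. In both CEH-60 lists of protocol 2 there were 0 peaks within 20 kb of pqm-1, so the label pqm-1(ok485) of DLS435 could not be checked. At unc-62, both lists of the gaIs285 strain had a single long peak, of 26170 bp for CEH-60 (V 4486589 to 4512758) and of 32132 bp for UNC-62 (V 4480676 to 4512807), and the longest there in any other list was 1815 bp. Within 20 kb of unc-119, which is mutated in OP201, the lists had 0 to 2 peaks.

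Peaks of all 3 factors lay between genes and on the X chromosome more often than the genome's make-up gives. In CEH-60 replicate 1, 56.8% of summits (95% interval 55.7 to 57.8%) lay outside every protein-coding gene, against 38.9% at random positions. Genes of other types were not counted, so between genes means outside protein-coding genes. At an end of a protein-coding gene lay 49.2% of summits, against 35.9%. The share between genes ran from 56.5% for PQM-1 in DLS422 to 62.4% for UNC-62. The X chromosome, which holds 17.7% of nuclear bases and 21.2% of bases between genes, held 24.6% of peaks in CEH-60 replicate 1, 27.4% for UNC-62, 25.3% for PQM-1 in OP201, 30.0% in CEH-60 replicate 2 and 31.9% in DLS435. Bound protein-coding genes numbered 5030 of 19971 in CEH-60 replicate 1, 2557 with mIgG1, 5099 in DLS396, 1235 for UNC-62, 3376 for PQM-1 in OP201, 2679 in DLS422, 1929 in CEH-60 replicate 2 and 1087 in DLS435. Every list bound elt-2, the GATA factor of the intestine, fat-2, a fatty acid desaturase, lys-8, a lysozyme, and ins-7, an insulin-like peptide gene.

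The 2 CEH-60 libraries from DLS395 made with 3F10 address how reproducible CEH-60 binding was, across protocols. The strongest peaks of replicate 1 that replicate 2 also had lay at ceh-60 itself (21.1-fold in replicate 1), vit-2 (20.99), the tubulin ligase-like gene ttll-9 (20.4, V 20909415 to 20910364), Y40H7A.10 (20.3, IV 15215283 to 15216066) and nssp-75 (20.0). They were followed by ttr-45, a transthyretin-like gene (19.9), fbxl-5, an F-box gene (19.5), the peak between srh-70 and the homeobox gene ceh-99 (19.03), abu-8 (18.7) and vit-1 (18.6). Replicate 1 alone had peaks at ugt-41, a glucuronosyltransferase gene (13.1), ctdh-1 (12.3), F53A9.9 (11.6), hzl-1 (11.2), the secreted protease gene adt-1 (10.8), tra-1, the zinc finger regulator of sex determination (10.7), nhr-57, a nuclear hormone receptor gene (10.6), and cyp-33C6, a cytochrome P450 gene (10.3). The strongest peaks of replicate 2 alone lay at the small heat shock gene sip-1 and its neighbours (2.40 in replicate 2), F25B5.5 (2.37), C42D8.9 (2.34), srw-85 (2.22), the transaldolase gene tald-1 with rpl-7A (2.13), the chitinase gene cht-1 (2.08) and dnj-13, a DnaJ chaperone gene (2.07). A peak unique to a list does not make its gene unique to it, since ctdh-1, tald-1, rpl-7A and dnj-13 were bound in both replicates through peaks at separate positions.

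Of the 3430 replicate 2 peaks, 3338 overlapped a replicate 1 peak by 1 bp or more, which is 97.3% (96.7 to 97.8%), against a mean of 8.02% when replicate 1 peaks were placed at random. In the other direction 3011 of 9008 peaks (33.4%) overlapped, and the share rose with fold, from 4.04% of the weakest quartile of replicate 1 to 82.9% of the strongest. Summits of overlapping peaks were a median of 31 bp apart. The libraries bound 1852 genes in common, against 485.8 for independent lists. With an overlap of at least 50% of both peaks required, the share was 52.2%. Because the replicates differ in crosslinking, shearing and library kit, the spread between libraries made in the same way was not measured.

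**Figure D2:**
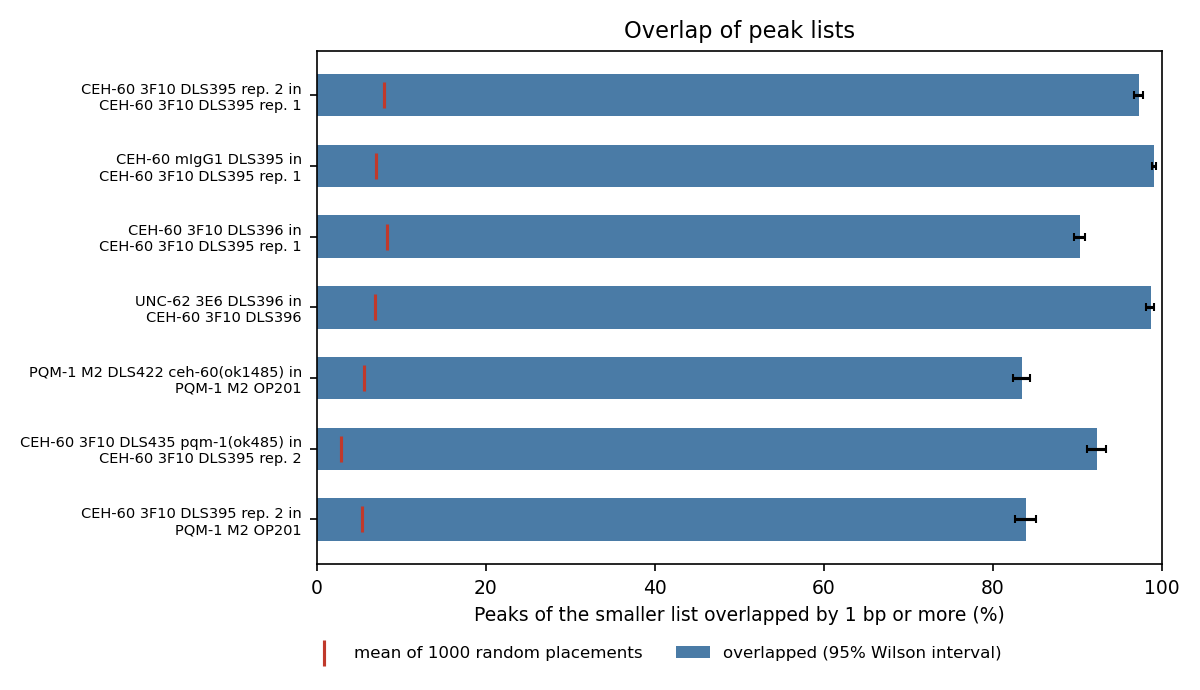
Share of the smaller peak list (horizontal axis, %) that overlaps a peak of the other list by 1 bp or more, for the 7 pairs of lists, with Wilson 95% intervals as error bars and the mean of 1000 random placements as red ticks. Shares run from 83.5% (PQM-1 with and without ceh-60) to 99.1% (2 antibodies to CEH-60), and the random means from 2.91% to 8.28%.

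CEH-60 replicate 1 bound genes of yolk production, lipid metabolism, innate immunity and intestinal function more often than random lists of equally spaced genes. All 12 intestine markers were bound (median of random lists 3), among them elt-2 (13.9-fold), cpr-6, a cathepsin B-like protease gene (13.1), the peptide transporter gene pept-1 (12.3) and vha-6 (9.10). Vitellogenins stood at 6 of 6 (random median 1), and regulators of vitellogenesis at 10 of 16 (4), with mab-3, a DM-domain factor that represses yolk genes in males, at 18.1-fold and the kinase gene sgk-1 at 7.73. Of the genes of fatty acid synthesis and desaturation, 17 of 26 were bound (7), including fat-2 (17.9), fat-7 (10.4), fat-1 (9.71) and the elongase gene elo-5 (9.19). Genes of fatty acid oxidation stood at 19 of 28 (7), with acox-1.1 (8.49), acdh-1 (7.94), dhs-28 (7.76) and daf-22 (7.73), and lipases at 9 of 16 (4), with lipl-5 (10.5) and the hormone-sensitive lipase gene hosl-1 (8.82). Innate immune effectors stood at 27 of 42 (11), with lys-8 (14.2), irg-2 (12.5), spp-5 (12.5) and lys-1 (11.9), and innate immune regulators at 9 of 12 (3), with nsy-1 (9.28) and pmk-1 (7.44), both kinases of the p38 pathway, and cebp-1 (7.28).

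Among gene families, all 10 dod genes, named for acting downstream of DAF-16, were bound (random median 3), with dod-23 at 17.3-fold and dod-3 at 10.6. Cytochrome P450 genes stood at 41 of 74 (19; cyp-35A3 15.3, cyp-34A10 14.4), glucuronosyltransferases at 41 of 67 (17; ugt-43 15.9) and glutathione S-transferases at 20 of 44 (11; gst-29 9.38). Nuclear hormone receptors stood at 106 of 269 (68; nhr-8 13.7), aspartyl proteases at 11 of 17 (4; asp-4 12.3) and vacuolar ATPase subunits at 10 of 20 (5; vha-13 7.25). Together with the lists above, 15 of 28 lists were above random lists, meaning that under 2.5% of 10000 random lists had as many bound members. In the shorter list of replicate 2, 9 of them were above. Those not above there were fatty acid oxidation (6 of 28, random median 3), lipases (3 of 16, 1) and cytochrome P450 genes (9 of 74, 7). Glutathione S-transferases (7 of 44, 4), nuclear hormone receptors (25 of 269, 26) and vacuolar ATPase subunits (1 of 20, 2) were not above either. Collagens, at 22 of 156 (40), and histones, at 7 of 72 (19), were below, although col-74 (12.8) and his-41 (6.62) were bound. The remaining lists were on neither side: lipid transport and binding 5 of 11 (3; lbp-5 10.4), C-type lectins 75 of 239 (61; clec-179 16.4), insulin-like peptides 10 of 38 (9; ins-7 15.01), heat shock proteins 7 of 24 (6; hsp-17 10.4), and ribosomal proteins 12 of 48 (12; rpl-27 11.2) for the rpl genes and 7 of 30 (7; rps-21 9.10) for the rps genes. Markers of other tissues were also on neither side, with 3 of 12 for body muscle (3; unc-60 7.87), 3 of 16 for neurons (4; egl-21 3.73), 3 of 16 for the germline (4; mex-5 8.05), 1 of 10 for the hypodermis (2; elt-3 4.93) and 1 of 7 for the pharynx (2; pha-4 8.35). Members of a family often lie side by side and can share a peak, which random lists do not copy.

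**Figure D3:**
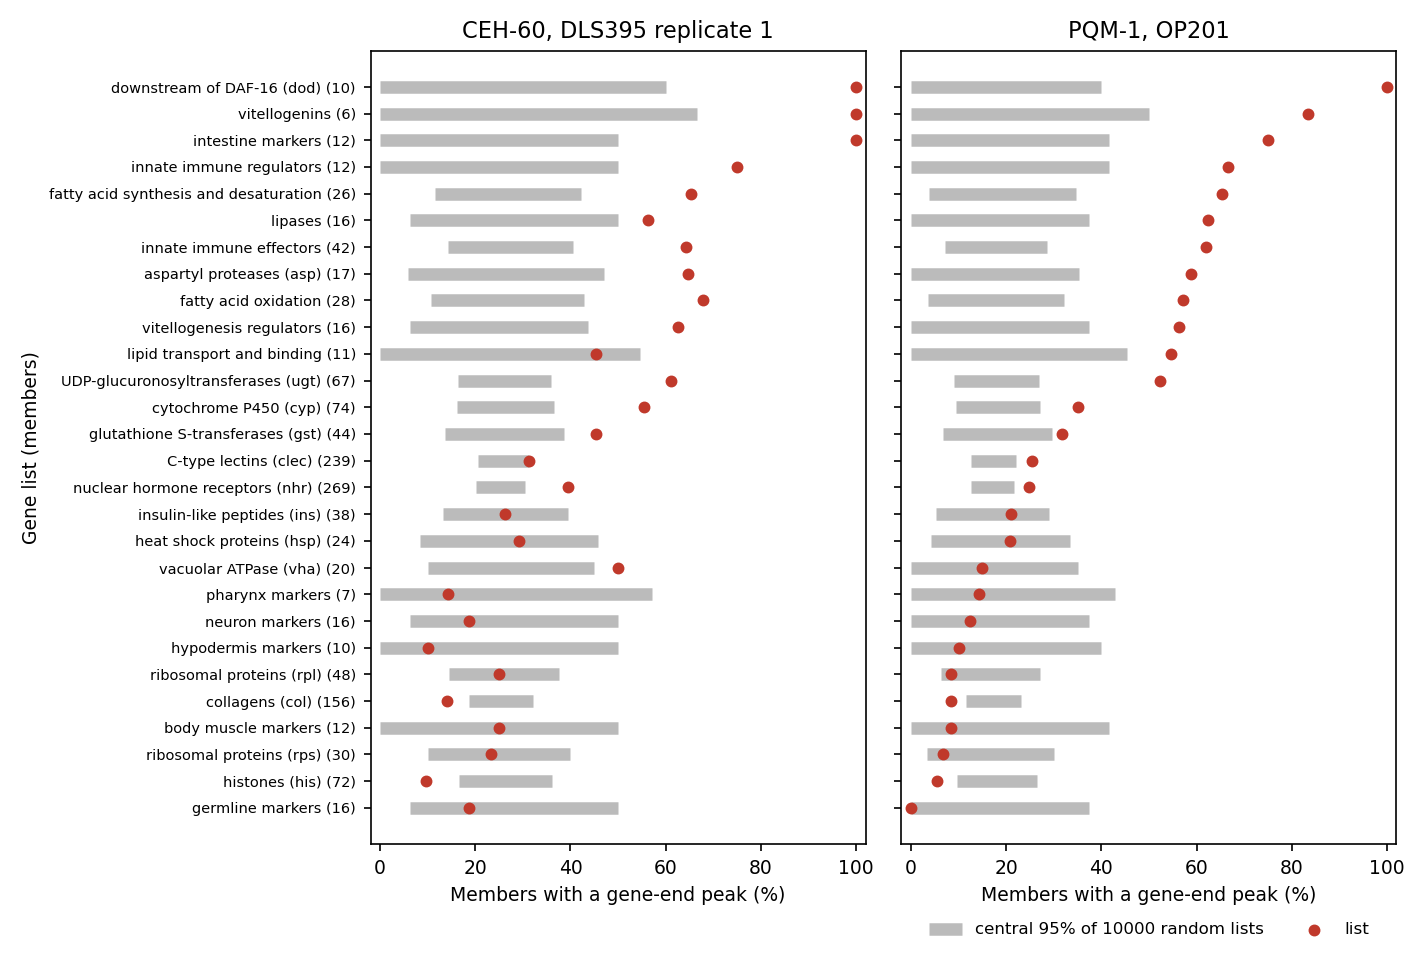
Members of each of the 28 gene lists with a peak at a gene end (horizontal axis, % of members; points) beside the central 95% of 10000 random lists (grey bars), for CEH-60 replicate 1 and for PQM-1 in OP201. Points lie above the random lists for 15 lists in CEH-60 replicate 1 and for 16 in OP201, and below for 2 in each.

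Recovery with mIgG1 asked whether a different antibody to the same tag finds the same CEH-60 sites. The vitellogenins were bound with both antibodies, and the mIgG1 peaks at these genes had folds of 13.7 to 21.1. Peaks found with 3F10 alone were led by the C-type lectin gene clec-218 (8.93), ZK6.8 (8.69), klo-1, a klotho homologue (8.14), the troponin T gene tnt-4 (8.08) and the cytochrome P450 genes cyp-13A8 (7.94) and cyp-33E2 (7.52). The few found with mIgG1 alone included clc-22 (3.64), the ammonium transporter gene amt-3 (3.60), gst-41 (3.60), ugt-40 (3.34) and the initiation factor gene eif-2Bgamma (2.62). ZK6.8, cyp-33E2 and eif-2Bgamma had a separate peak with the other antibody. Of 4429 mIgG1 peaks, 4390 (99.1%, 98.8 to 99.4%) overlapped a replicate 1 peak, against 7.07% at random, and 39 did not. In the other direction 4079 of 9008 (45.3%) overlapped, from 5.15% of the weakest quartile by fold to 97.3% of the strongest. The mIgG1 list had 10 of 28 gene lists above random lists, among them the vitellogenins, fatty acid synthesis, immune effectors, intestine markers and glucuronosyltransferases, and collagens below. With an overlap of 50% of both peaks the share was 57.1%.

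The CEH-60 list of DLS396 gives CEH-60 binding in animals that also carry the unc-62 transgene. Peaks unique to DLS395 replicate 1 were weak apart from that shared by gfi-1 and bcf-1 (8.26), and were otherwise led by arrd-1, an arrestin domain gene (4.31), srh-300 (4.18), bgnt-1.4 (4.04), the synaptic liprin gene syd-2 (3.98) and clec-100 (3.97). Those unique to DLS396 were led by fbxa-106 (9.73), ncl-1, a regulator of nucleolar size (5.78), F35B3.7 (5.68), the staufen homologue stau-1 (5.63), ugt-40 (5.41), the Sm protein gene snr-7 (5.36) and col-143 (5.29). Of these genes, gfi-1, bcf-1, clec-100 and ncl-1 were bound in the other strain at a separate position. At the vitellogenins the DLS396 folds were 24.5 to 31.5. Of 8991 DLS396 peaks, 8117 (90.3%, 89.7 to 90.9%) overlapped a DLS395 peak, against 8.28% at random, and 8101 of 9008 DLS395 peaks (89.9%) overlapped in return. The strains bound 4608 genes in common, against 1284 for independent lists, and summits were a median of 19 bp apart. In DLS396, 14 of 28 gene lists were above random lists, with collagens and histones below.

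CEH-60 and UNC-62 were recovered from the same strain to ask where both proteins bind. The strongest CEH-60 peaks of DLS396 that UNC-62 shared lay at ceh-60 (33.4-fold for CEH-60, X 6530212 to 6531540), Y40H7A.10 (33.3), ttr-45 (31.7), vit-2 (31.5), ttll-9 (31.3), srh-70 with ceh-99 (30.9), nssp-75 (30.7), the leucine-rich repeat gene lron-7 (30.3), F32B5.6 (30.0) and pha-2, a homeobox gene of the pharynx (29.4). Within the UNC-62 list, vit-2 (13.3), ceh-60 (13.04), clec-179 (12.7), vit-3 (12.6), vit-6 (12.01), fat-2 (11.1) and mab-3 (10.5) had high folds. CEH-60 peaks without UNC-62 were led by the chemoreceptor gene str-264 (19.3), the ammonium transporter gene amt-4 (18.7), srdf-2.1 (18.4), clec-78 (17.7), W06D11.2 (16.3), baz-2 (15.9), aaim-1 (15.8), gpdh-1, a glycerol phosphate dehydrogenase gene of the osmotic stress response (15.4, I 14075558 to 14075959), and the ATPase gene ruvb-2 (15.3). Just 26 UNC-62 peaks lacked CEH-60, among them those at Y97E10AL.1 (3.44), aps-3 with znf-236 (3.22), T28H10.2 (3.08), rsp-8, a splicing factor gene, with ntl-3 (3.03), and tent-5 (3.03). At amt-4, aps-3 and T28H10.2 the other factor had a separate peak.

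Of 2051 UNC-62 peaks, 2025 (98.7%, 98.2 to 99.1%) overlapped a CEH-60 peak, against 6.90% at random positions and 7.33% at random gene ends. Summits were a median of 22 bp apart, and 1193 genes were bound by both, against 315.3 for independent lists. In return, 1884 of 8991 CEH-60 peaks (20.95%) overlapped an UNC-62 peak, from 0.756% and 1.02% of the 2 weaker quartiles of CEH-60 fold to 11.9% and 70.2% of the stronger ones. UNC-62 bound 10 of 28 gene lists above random lists: the vitellogenins at 6 of 6 (random median 0), vitellogenesis regulators at 4 of 16 (1), lipid transport at 4 of 11 (1), fatty acid synthesis at 11 of 26 (2), immune effectors at 8 of 42 (3; lys-8 6.97, irg-2 6.08), immune regulators at 5 of 12 (1), intestine markers at 5 of 12 (1), dod genes at 3 of 10 (0; dod-23 8.0), cytochrome P450 genes at 12 of 74 (5; cyp-35A3 9.53) and glucuronosyltransferases at 19 of 67 (4; ugt-49 8.34). Fatty acid oxidation genes, at 3 of 28 (2), and nuclear hormone receptors, at 23 of 269 (17; nhr-35 6.41), were on neither side in this shorter list. With an overlap of 50% of both peaks, 21.1% of UNC-62 peaks were shared. A list from animals without a tag was not used here, so sites that any antibody recovers were not set apart.

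**Figure D4:**
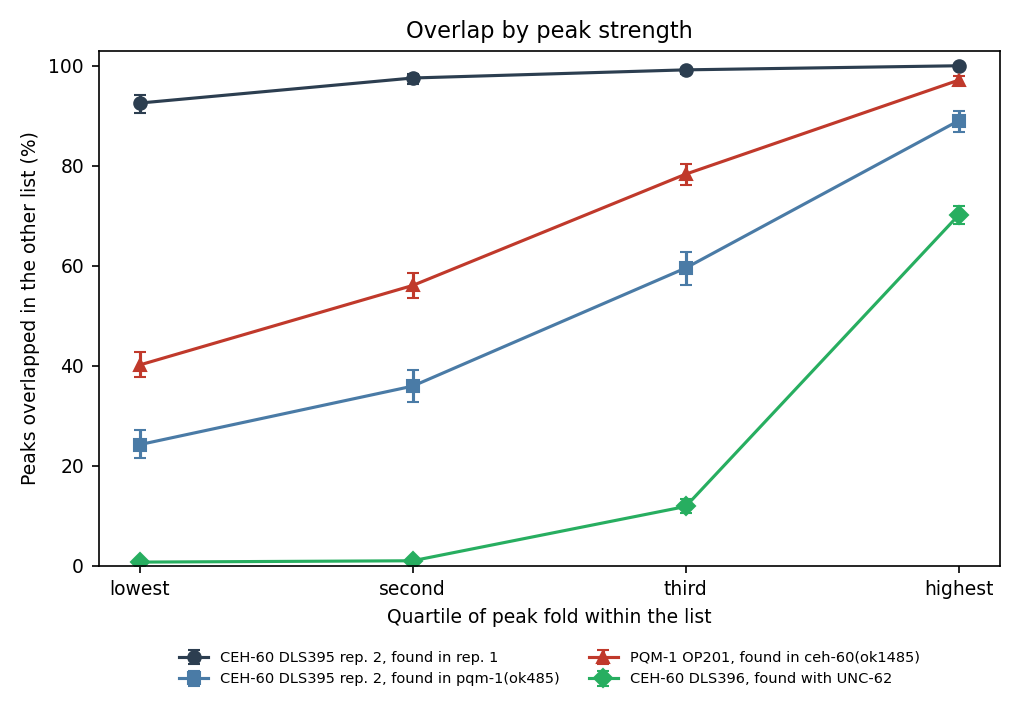
Share of peaks that another list also has (vertical axis, %) by quartile of fold within the list, from weakest to strongest (horizontal axis), with Wilson 95% intervals as error bars. The share rises with fold in each line, from 40.2% to 97.1% for PQM-1 peaks of OP201 in DLS422 and from 0.756% to 70.2% for CEH-60 peaks of DLS396 in the UNC-62 list.

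PQM-1 and CEH-60, set side by side within protocol 2, show where the yolk regulator and the intestinal zinc finger factor occupied the same sites. Both bound vit-1 to vit-5, ceh-60, elt-2 and irg-4. The strongest CEH-60 peaks without PQM-1 lay at C13B9.2 (3.65-fold for CEH-60), the myosin light chain kinase gene mlck-1 (3.53), math-16 (3.46), hsd-3, a hydroxysteroid dehydrogenase gene (3.42), the acetylcholinesterase gene ace-1 (3.37), drd-10 (3.31), the kinase gene pak-1 (3.29) and cyp-34A10 (3.20). PQM-1 peaks without CEH-60 were led by ani-3, an anillin gene (3.88 for PQM-1), the cohesin loader gene scc-2 (3.81), the amino acid transporter gene aat-7 (3.75), cyp-37B1 (3.75), madf-6 (3.74), btb-9 (3.74), the nuclear receptor genes nhr-130 (3.68) and nhr-69 (3.62), and clec-55 (3.64). Of 3430 CEH-60 peaks, 2878 (83.9%, 82.6 to 85.1%) overlapped a PQM-1 peak, against 5.39% at random, and 2697 of 6001 PQM-1 peaks (44.9%) overlapped a CEH-60 peak. The factors bound 1672 genes in common, against 326.1 for independent lists. The share was 55.2% with an overlap of 50% of both peaks and 53.2% among the 1000 strongest peaks of each list.

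PQM-1 in OP201 bound 16 of 28 gene lists above random lists. Fatty acid synthesis stood at 17 of 26 (random median 4), with elo-1 (4.02-fold), fat-7 (3.55), nhr-80 (3.51) and elo-5 (3.42), fatty acid oxidation at 16 of 28 (5), with hacd-1 (3.24) and dhs-28 (3.12), lipases at 10 of 16 (3), with lipl-5 (3.60), and lipid transport at 6 of 11 (2), with lbp-5 (3.19) and lbp-8 (2.85). Immune effectors stood at 26 of 42 (7), with irg-4 (4.22), lys-8 (4.15), spp-3 (4.10) and irg-2 (3.91), and immune regulators at 8 of 12 (2), with pmk-1 (3.41) and nsy-1 (3.16). Intestine markers stood at 9 of 12 (2; cpr-6 3.82, pept-1 3.56, act-5 3.50), vitellogenins at 5 of 6 (1) and vitellogenesis regulators at 9 of 16 (3; ceh-60 3.96, daf-16 3.37). The dod genes stood at 10 of 10 (2; dod-21 4.32), cytochrome P450 genes at 26 of 74 (13; cyp-37B1 3.75), glucuronosyltransferases at 35 of 67 (12; ugt-62 4.31), glutathione S-transferases at 14 of 44 (8; gst-42 3.43), C-type lectins at 61 of 239 (41; clec-186 4.30), nuclear hormone receptors at 67 of 269 (46; nhr-8 4.61) and aspartyl proteases at 10 of 17 (3; asp-6 3.61). Collagens, at 13 of 156 (27; col-38 3.29), and histones, at 4 of 72 (13; his-41 3.15), were below random lists. On neither side were insulin-like peptides at 8 of 38 (6; ins-1 3.64), heat shock proteins at 5 of 24 (4; hsp-3 3.10), vacuolar ATPase subunits at 3 of 20 (3; vha-6 2.52), the rpl genes at 4 of 48 (8), the rps genes at 2 of 30 (5), and the markers of body muscle at 1 of 12 (2), neurons at 2 of 16 (3), germline at 0 of 16 (3), hypodermis at 1 of 10 (2) and pharynx at 1 of 7 (1).

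Sites of all 3 factors were counted among the 3011 CEH-60 peaks of replicate 1 that replicate 2 also had. Both UNC-62 and PQM-1 peaks overlapped 1409 of them (46.8%, 45.0 to 48.6%), UNC-62 alone 135 (4.48%), PQM-1 alone 1172 (38.9%) and neither 295 (9.80%). Placement at random gave a mean of 6.47 peaks with both, and placement at random gene ends 11.7. If UNC-62 and PQM-1 peaks fell independently among these CEH-60 peaks, 1324 would have both, fewer than the 1409 found. PQM-1 peaks overlapped most of these CEH-60 peaks whether or not UNC-62 did. The 135 with UNC-62 alone are the most by which the count with both could have been higher. The value of 1324 takes no account of fold. From the weakest to the strongest quartile of CEH-60 fold, overlap rose from 0.756% to 70.2% for UNC-62 (DLS396). For PQM-1 it rose from 78.4% to 90.2% (replicate 2). The excess over 1324 therefore does not show a tie between UNC-62 and PQM-1. The vitellogenin peaks at vit-1 to vit-5, and those at ceh-60 and elt-2, had all 3 factors by the gene-end rule. The share was 10.1% with an overlap of 50% of both peaks and 17.7% over all replicate 1 peaks, without replicate 2.

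PQM-1 in DLS422 against OP201 asks which PQM-1 sites were still found without ceh-60. PQM-1 peaks at vit-1 to vit-5 were found in OP201 and not in DLS422, 0 of 5. Of the strongest gene-end peaks of all genes bound in OP201, 70.7% were found. Of the OP201 peaks at genes of fatty acid synthesis 15 of 16 were found in DLS422, of those at immune effectors 22 of 24, at aspartyl proteases 9 of 9, at intestine markers 8 of 9 and at dod genes 8 of 10. Fewer were found at fatty acid oxidation genes, 8 of 15, lipases, 6 of 10, immune regulators, 5 of 8, and vacuolar ATPase subunits, 1 of 3. None of these 9 lists was called apart from fold-matched draws, which gave means of 21.1 for immune effectors, 8.27 for dod genes and 9.89 for fatty acid oxidation. The strongest peaks in both lists lay at the chemoreceptor gene srz-62 (6.65-fold in OP201, IV 3899578 to 3901041), oatr-1, an ornithine aminotransferase gene (5.47), scav-6, a scavenger receptor gene, with spsp-1 (5.42), Y75B8A.28 (5.33), the P-glycoprotein gene pgp-1 (5.09), B0507.3 (5.09), fbxc-50 (5.08) and pals-17 (4.99). OP201 peaks not found in DLS422 were led by Y40H7A.10 (3.75, IV 15215512 to 15215853), the astacin protease gene nas-29 (3.52), gldi-3 (3.48), chil-14 (3.39), atfs-1, the factor of the mitochondrial unfolded protein response (3.26, V 14193442 to 14193781), and nsy-1 (3.16, II 5022356 to 5022672). Peaks in DLS422 alone lay at clec-75 (3.03 in DLS422), the elongase gene elo-9 (3.01), the calmodulin-related gene cal-1 (2.95), arrd-11 (2.70), scl-23 (2.67), math-37 (2.63) and clec-174 (2.60). Through separate peaks, gldi-3, clec-75, elo-9, cal-1 and math-37 were bound in both strains.

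Of 6001 OP201 peaks, 4076 (67.9%, 66.7 to 69.1%) overlapped a DLS422 peak and 1925 did not. In return, 4189 of 5020 DLS422 peaks (83.5%, 82.4 to 84.5%) overlapped an OP201 peak, against 5.55% at random, and 831 did not. The share found rose with fold, from 40.2% of the weakest quartile of OP201 to 97.1% of the strongest. For the 5 vitellogenin peaks, draws of OP201 gene-end peaks matched on fold gave a mean of 3.93 found in DLS422, and 0 of 10000 draws gave as few as 0. This test by gene list was chosen after the values were seen, and of 112 such tests in 5 comparisons, each with a chance of up to 2.5% on either side, 3 lists were called below, the vitellogenins among them, and 1 above. Cytochrome P450 genes stood at 12 of 22, with 15.7 expected, and were not called. In DLS422, 12 of 28 gene lists were above random lists, among them intestine markers at 9 of 12, fatty acid synthesis at 18 of 26 and immune effectors at 25 of 42 (lys-8 4.05), while vitellogenins stood at 0 of 6 (random median 1). No second PQM-1 library of either strain was analysed here, and OP201 also differs from DLS422 by unc-119(tm4063).

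CEH-60 in DLS435 against replicate 2 asks the reverse, which CEH-60 sites were still found without pqm-1. All 6 vitellogenins were bound in both lists, and vit-5 (3.69-fold) and ceh-60 (3.59) had high folds within DLS435. The other vitellogenin peaks ranked from 530 (vit-6) to 1600 (vit-3) among 2048. Those at vit-2 (2.23) and vit-3 (2.02) lay below the median fold of DLS435, 2.28. Of 12 CEH-60 peaks at immune effectors, 11 were found in DLS435 (9.12 expected from fold-matched draws), with irg-2 at 3.26-fold there. Immune regulators stood at 2 of 6, glutathione S-transferases at 1 of 6 and fatty acid oxidation genes at 1 of 5. Of the strongest gene-end peaks of all bound genes, 52.9% were found. No list was called apart from the draws. The strongest peaks in both lists lay at K08H2.10 (5.42 in replicate 2), srz-62 (5.15), the C-type lectin gene clec-72 (4.90), Y40H7A.10 (4.88), B0348.1 (4.86), the dehydrogenase gene dhs-26 (4.70), C33G3.4 (4.70) and dod-23 with the peroxidase gene skpo-1 (4.61). Replicate 2 peaks not found in DLS435 were led by gldi-3 (3.78), C13B9.2 (3.65), dhhc-1 (3.33), drd-10 (3.31), hsd-2, a hydroxysteroid dehydrogenase gene (3.10), and the helix-loop-helix gene hlh-19 (3.10). Those in DLS435 alone included the saposin-like gene spp-18 (2.32 in DLS435), nhr-119 (2.26), egl-27 (2.25), the ferritin gene ftn-2 (2.21) and let-413, a gene of epithelial polarity (2.20). Both lists bound dhhc-1, egl-27 and ftn-2 through separate peaks.

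Of 2048 DLS435 peaks, 1891 (92.3%, 91.1 to 93.4%) overlapped a replicate 2 peak, against 2.91% at random, and 157 did not. In return 1790 of 3430 replicate 2 peaks (52.2%, 50.5 to 53.9%) overlapped a DLS435 peak, from 24.2% of the weakest quartile by fold to 89.03% of the strongest. The lists bound 1028 genes in common, against 105.0 for independent lists. In DLS435, 9 of 28 gene lists were above random lists, among them vitellogenins at 6 of 6, fatty acid synthesis at 7 of 26 (fat-2 3.10) and aspartyl proteases at 6 of 17 (asp-4 3.20), the same number of lists as in replicate 2. Fatty acid synthesis, immune effectors, intestine markers and glucuronosyltransferases were above random lists in each of the 8 libraries. Most replicate 2 peaks absent from DLS435 were weak in replicate 2, and the shorter DLS435 list limits what their absence shows.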

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

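The count of mitochondrial peaks was chosen only after they were seen. The mitochondrial chromosome, which no comparison used, held 8 peaks, 2 in each of the 4 lists of protocol 1, with folds of 4.62 to 8.99, and 0 in the 4 lists of protocol 2. The 2 peaks of each such list were long stretches that together covered 13175 to 13266 bp, and not narrow sites. They were listed because they are a signal outside the nuclear peaks compared, and no biological explanation was tested.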

How the results depend on the processing

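The alternatives of random gene ends, draws by decile of −log10 q, draws of peaks with a −log10 q of 5 or more, vit-5 alone of the copies vit-3, vit-4 and vit-5, CEH-60 replicate 1 as the partner list and replicate 2 peaks that replicate 1 also has were chosen only after the results were seen. Of 126 alternative values, 98 were counted as the same and 28 as moved, and no test for a reversal was run. For the 114 planned values, the same meant within their interval or within 1.5 times. Among the 12 added values, chance levels were judged by the largest random placement and vitellogenin draws by the share of draws as low. The value with CEH-60 replicate 1 as the partner list was counted as moved without such a rule. The cause of the moves was not tested, except that a stricter overlap can only remove shared peaks. With an overlap of at least 50% of both peaks, the shares were 52.2% for the CEH-60 replicates, 57.1% for the antibodies, 85.1% for the strains, 21.1% for UNC-62 in CEH-60, 65.8% for PQM-1 with and without ceh-60, 72.1% for CEH-60 with and without pqm-1, 55.2% for CEH-60 in PQM-1 and 10.1% for all 3 factors. Among the 1000 strongest peaks of each list, in the same order, they were 66.5%, 77%, 85%, 82.3%, 68.5%, 73.2%, 53.2% and 40.2%. With a −log10 q of 5 or more, the replicates shared 98.2%, PQM-1 84.95%, and the share of summits between genes was 60.4% in OP201 and 58.9% in DLS422. Without peaks near structural RNA genes, the share was 96.6% for the replicates, 98.6% for the antibodies and 97.7% for UNC-62. Leaving out a CEH-60 replicate gave 17.7% to 43.5% for all 3 factors. With 2000 bp outside gene ends UNC-62 bound 1865 genes, and 1 vitellogenin was bound in DLS422. Of the added alternatives, PQM-1 peaks with a CEH-60 replicate 1 peak were kept at 73.2% without ceh-60, with 72.2% expected from fold-matched draws, against 85.1% and 80.8% for replicate 2, and CEH-60 replicate 2 peaks that replicate 1 also has were kept at 53.2% without pqm-1. The motif alternatives were not run. No paired analysis was possible because the results come from lists of 1 library per arm, which also rules out leaving out a replicate elsewhere. Unknown read depth limits what the absence of a peak shows.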

Other observations

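The tests by gene list in this part, and all tests of explanations except those of extra pqm-1 copies and of weak peaks around pqm-1, were chosen only after the result was seen. Replicate 1 peaks of CEH-60 at some families were found in replicate 2 less often than fold-matched draws of gene-end peaks, in 26 lists tested. Of 33 peaks at cytochrome P450 genes 8 were found, with 15.2 expected, and of 98 at nuclear hormone receptors 19, with 32.7 expected, and 0 of 10000 draws gave as few for either. Heat shock genes went the other way, with 4 of 7 found and 2.02 expected. PQM-1 peaks of OP201 were set beside CEH-60 replicate 2 peaks in the same way, in 21 lists tested. Overlap was less frequent than in draws at nuclear hormone receptors, 18 of 60 with 27.4 expected, and 16 of 10000 draws gave as few. The same held at immune effectors, 11 of 24 with 16.6 expected, and 49 draws gave as few. PQM-1 peaks at vitellogenins overlapped in 5 of 5, with 2.70 expected, and 233 of 10000 draws gave as many. Those 5 peaks count the near-identical copies vit-3, vit-4 and vit-5 separately, so this excess rests on fewer than 5 independent loci.

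Across the 8 lists, 601 genes were bound in each and 14013 in none, and of 10814 merged regions 936 had a peak in every list. Genes bound in every list included the lipid-binding gene lbp-5, the cathepsin-like protease gene asp-4, the lipase gene lipl-5, the fat regulator sbp-1, and nhr-8 and nhr-35. Single members of families that were not above random lists were also bound in every list, as rpl-27 and rps-21 of the ribosome, ins-1 and ins-7 of the insulin-like peptides, col-180 of the collagens and his-41 of the histones. Of the germline marker mex-5, a zinc finger gene of the embryo, CEH-60 had a peak in 4 lists (8.05-fold in replicate 1) and PQM-1 had none.

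PQM-1 peaks at vit-1 to vit-5 were found in OP201 and not in DLS422, the strain without ceh-60. Weak peaks below the DLS422 threshold are argued against, since fold-matched draws kept 3.93 of 5 on average and 0 of 10000 kept none. With vit-5 alone of its copies, draws kept 2.66 of 3 on average and 6 kept none. Those 3 peaks still count vit-2, and vit-1 with vit-5 alone was not tested. Of the copies, vit-5 had the highest OP201 fold, 3.03 against 2.75 at vit-4 and 2.13 at vit-3. The share kept rises with fold, so this choice raises the number expected, and neither vit-3 nor vit-4 was tested in its place. A loss of PQM-1 wherever CEH-60 also binds is argued against too, since 85.1% of PQM-1 peaks with a CEH-60 peak were kept, against 80.8% in matched draws. Signal along transcribed gene bodies is argued against at vit-1, vit-3, vit-4 and vit-5. PQM-1 summits there lay within 25 bp of those of CEH-60, and OP201 peaks covered 14.8% of vit-5 and less of the others. At vit-2 and vit-6 the PQM-1 summits lay 229 bp or more away with peaks over most of the gene, as such signal would give. CEH-60 replicate 1 peaks covered 93.6% of vit-1, 93.9% of vit-2, 70.04% of vit-5 and 100% of vit-6. They covered 31.9% of vit-3 and 17.97% of vit-4. CEH-60 peaks of the mIgG1 library covered 32.72% of vit-6 and less of the others. Whether such signal adds to the CEH-60 peaks was not tested. A hypothesis is that PQM-1 may need CEH-60 at the vitellogenin genes. It was prompted by these same PQM-1 peaks, and no independent test of it was run. Further PQM-1 libraries of both strains would be needed to decide it. Differences between 1 library of each strain, unc-119(tm4063) and reads shared among vit-3, vit-4 and vit-5 stay open, so the pattern is not called biological.

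Both lists of the strain with gaIs285 had a long peak at unc-62, of 26.2 kb for CEH-60 and 32.1 kb for UNC-62, from different antibodies, with right ends 49 bp and left ends 5913 bp apart. Without the transgene, CEH-60 peaks covered 23.8% of unc-62, which argues against CEH-60 binding along the whole gene in that strain. No UNC-62 list from a strain without gaIs285 was used here, so UNC-62 binding along the gene could not be tested. Nor could CEH-60 binding that depends on gaIs285. The longest peak there in the lists of other strains was 1815 bp, which is consistent with extra copies of unc-62 in gaIs285 raising the signal in any immunoprecipitate. The structure and copy number of the transgene were not measured. The input sample of protocol 1 came from DLS395, which lacks gaIs285, and whether it was the control for these lists is not given in the sources used here.

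Neither CEH-60 list of protocol 2 had a peak in a 258 kb stretch around pqm-1 (II 10949644 to 11207667), where replicate 1 had 15 and 3.41 were expected from their fold, and where the PQM-1 lists of the same protocol had 9 (OP201) and 6 (DLS422). The pqm-1 deletion is carried by DLS435 and not by DLS395, and its part in the DLS435 list was not tested. By the bounds set before the result, rank 12 among 3567 stretches (0.336%) would have favoured extra copies of pqm-1 in the control library, and no recovered peak in 0.64% of draws would have argued against weak peaks. Both readings were then left open, because the limits of the stretch were themselves set by the absence of peaks, 11 stretches without a tagged gene ranked higher, 9 others had as low a chance, and 258 kb is far wider than a transgene. Extra copies and weak peaks cannot be told apart here. The input sample of protocol 2 came from OP201, which carries wgIs201, but the control library of each call is not given in the sources used here.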
